A study of Mus musculus with 6 samples.

How the data were processed

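Gene expression was measured on 6 Affymetrix arrays, 1 per macrodissected brain lesion. There were 3 lesions of wild type mice and 3 of transgenic mice, in which non-proliferating GFAP-positive astrocytes can be removed. The value table pairs each column with a sample by its accession, and the group and replicate number of each sample come from its title. No sample was left unassigned and 0 columns belonged to unknown samples.

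The deposited values are intensities that the authors had normalized by RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, makes the probe distributions of the arrays equal and summarises the probes of each probe set. It gives log2 values, whereas the deposited intensities were on a linear scale, with array medians from 40.4 to 48.3 and array maxima from 14197 to 15794. They were therefore turned to log2 before any test, with no pseudocount because the lowest value was 3.73. Versions, the genome build, detection calls and scan dates are not given in the sources used here, so neither a detection filter nor a batch term could be applied. After summarising, the distributions were no longer exactly equal. The median log2 intensity was 5.34 in transgenic replicate 2 and lay between 5.52 and 5.59 on the other arrays.

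The table held 41345 probe sets. The platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010. Genes were named only from probe sets with 1 symbol, which covered 22180 genes. Of these probe sets, 23328 matched a gene number in the RefSeq gene table of assembly GRCm38.p6, and no symbol changed by that match. The table gave chromosomes for an autosomal subset of 22332 probe sets and no coordinates are reported, since the build behind the arrays is unknown. No prefix or annotation marked control probe sets, so all 41345 entered the test, the unnamed ones included.

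The groups were compared with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes on the log2 intensities, with the difference coded as transgenic minus wild type, a two-sided moderated test and Benjamini-Hochberg adjustment over all probe sets at a threshold of 0.05. All 6 arrays entered the fit without a covariate. Standard errors are those of the fit and SDs are over the 3 arrays of a group. Unless another adjustment is named, an adjusted p beside a gene is from this fit. The number of arrays limits the precision: the median standard error of a log2 difference was 0.19, and the median half-width of its 95% confidence interval was 0.45, a 1.36-fold difference. A further count used probe sets with an unadjusted p under 0.05 and at least a 1.5-fold difference.

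Gene lists for 34 cell types and processes, with 424 different genes, were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Of their genes, 378 had a probe set with 1 symbol, and each gene was read from its probe set with the highest mean over the 6 arrays. The 33 lists with at least 3 measured members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. The erythrocyte list had 0 such members and was not tested. Every list was tested again with the correlation estimated from the data and with fry, which tests whether a list moves one way on balance. Members were also counted when adjusted over the list alone. The mean of a list on each array was compared by an exact two-sided permutation test over the 20 assignments of 3 against 3, which cannot give a p below 0.1. Genes were named by this rule: in each direction, the 10 probe sets with 1 symbol whose groups did not overlap, by adjusted p and then, where fewer than 10 passed, by unadjusted p; 12 fixed genes of astrocytes, oligodendrocytes, microglia and apoptosis; and up to 4 members of each list with the smallest unadjusted p. Of the 12 fixed genes, 11 were analysed and 1 is not reported here.

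The limma step was tested on simulated data with the real means of 41345 probe sets, 6 arrays and 200 changed probe sets. Noise was independent and normal, with the moderated SD of each probe set, equal in both groups. The limma step recovered 37 of 100 probe sets changed by 1 on the log2 scale and 94 of 100 changed by 2, with 9 false calls. The real groups differed in spread, with a median SD of 0.15 in wild type and 0.26 in transgenic lesions. These rates may therefore not hold for the real arrays. In a simulation over 22180 genes with independent noise, camera called a myelin list shifted by -0.5 at an adjusted p of 8.58e-23 and called 0 of 32 unshifted lists. With an estimated correlation the adjusted p of the shifted list was 0.0125. Genes of the real lists were correlated, at an estimated 0.46 in the myelin list and 0.97 in the striatal list. The simulation therefore does not show how often camera calls unshifted lists in these data.

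Alternatives covered further normalization (quantile, median centring), filters on dim probe sets at the 25th and 50th percentiles, 1 probe set per gene, eBayes with trend and robust, array weights, the replicate number as a block, a plain t-test, an adjusted threshold of 0.10, the mean of a gene's probe sets and leaving out each array. Those with sex, with the striatal or cortical list mean, with subsets of arrays or with autosomal probe sets alone were chosen after seeing the data.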

Results

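The study asked what astrocytes contribute to early myelin repair. Demyelinating lesions were made in the brains of mice aged 5 to 6 weeks with LPC, a lipid that strips myelin locally. CID, the compound that sets off astrocyte ablation in the transgenic mice, was injected 48 hours later, and the lesions were collected 7 days after the lesion. The labels give the same treatment for both genotypes. Total RNA of each macrodissected lesion was hybridised to 1 array, with 3 wild type and 3 transgenic lesions. Nothing states whether the 3 lesions of a group came from separate animals, so p-values measure only the spread between these samples. Levels below are log2 intensities of RMA values and differences are transgenic minus wild type.

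The wild type arrays resembled each other more than the transgenic arrays did. Across probe sets, Pearson correlations were 0.980 to 0.984 within the wild type group, 0.928 to 0.968 within the transgenic group and 0.949 to 0.972 between the groups. The median SD of a probe set was 0.15 in wild type and 0.26 in transgenic lesions. The first principal component, with 39.3% of the variance, set transgenic replicates 1 and 2 at opposite ends. The second, with 30.4%, separated the groups, at 28.98 to 43.81 in wild type and -48.44 to -23.63 in transgenic lesions.

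The comparison of transgenic with wild type lesions asks which transcripts differ once astrocytes have been targeted. Among the genes named for the smallest p-values with groups that did not overlap, those higher in transgenic lesions included Vip, a neuropeptide of cortical interneurons, Mgp and Dcn, both of the extracellular matrix, Dusp6, a phosphatase that acts on ERK, and Pvalb, the calcium-binding protein of another interneuron class. Vip stood at 7.77 ± 0.11 (SD, n = 3) in wild type and 8.99 ± 0.10 in transgenic lesions, a 2.34-fold difference. Mgp was 2.47-fold, Dcn 2.67-fold, Dusp6 2.38-fold and Pvalb 2.66-fold higher. The lower side included Tspan2, a tetraspanin of oligodendrocytes, at 10.26 ± 0.25 against 9.25 ± 0.14, a 2.02-fold difference, and Gpr37, a receptor of myelinating oligodendrocytes, 1.94-fold lower. Thbs4, a thrombospondin made by astrocytes among other cells, was 2.18-fold lower, and Tmem88b was 2.12-fold lower. None of these genes passed the adjusted threshold with all 6 arrays, and their adjusted p-values in limma lay between 0.21 and 0.29.

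The remaining genes named by the same rule were Eif4a2 (difference 1.10), Snora23 (1.12), Slc23a2 (0.77), Hsd3b3 (1.06) and Cntn6 (0.86) on the higher side. On the lower side they were Btbd35f5 (-1.64), Usp17le (-0.90), H2ac10 (-0.87), Trim59 (-0.98), Speer4c (-0.84) and Pramel21 (-1.10). Their adjusted p-values in limma also lay between 0.24 and 0.28. Hsd3b3, Btbd35f5, Usp17le, H2ac10, Speer4c and Pramel21 belong to multigene families whose near-identical copies can share probes, so these values are uncertain. The 3 probe sets of Eif4a2 disagreed, with 2 higher and 1 lower.

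No probe set of 41345 passed the adjusted threshold of 0.05 in limma, where the smallest adjusted p was 0.213. A test without the moderation of variances, adjusted in the same way, also gave 0. At an unadjusted p under 0.05, 3668 probe sets (8.87%) differed, 1992 higher and 1676 lower, where chance alone gives 2067. Of these, 1950 differed at least 1.5-fold, 990 higher and 960 lower. The groups did not overlap for 16.1% of probe sets, where chance gives 10%. With array weights 2611 passed, in a fit that rested mostly on transgenic replicate 3 within its group. Without transgenic replicate 2, which left male transgenic against female wild type arrays, 335 passed, of which 263 were higher and 72 lower. Of the 45 of these probe sets with 1 gene symbol, 22 were on the Y chromosome, 7 on the X chromosome and 0 in the myelin list. Autosomal genes named above also passed there: Dcn (adjusted p 0.0178), Vip (0.0183), Dusp6 (0.0277), Eif4a2 (0.0381) and Mgp (0.0406) were higher and H2ac10 (0.0343) was lower. These genes had been chosen for small p-values on the same arrays, so their passing is no separate support. Genotype and sex coincided in this subset, so a difference of sex is not set aside for them either. The unadjusted count was 2031 without wild type replicate 1 and 2253 without wild type replicate 2.

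Transcripts of myelin and of mature oligodendrocytes, the cells that make it, were lower in the transgenic lesions. All 19 measured members of this list had lower means, with a median difference of -0.80. Ermn, a cytoskeletal protein of myelinating cells, stood at 10.21 ± 0.33 in wild type and 9.03 ± 0.30 in transgenic lesions (SD, n = 3), a 2.27-fold difference. Mag, an adhesion molecule of the inner myelin membrane, was 2.26-fold lower (difference -1.17, SE 0.25) and Myrf, the transcription factor of the myelination programme, 1.83-fold lower (-0.87, SE 0.18). Mbp, which compacts the myelin sheath, was 1.75-fold lower (-0.80, SE 0.31) and Mog, a surface protein of myelin, 1.79-fold lower (-0.84, SE 0.24).

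Adjusted over the list alone, 17 of the 19 fell and none rose; over all probe sets, 0 passed. In 15 of the 19, every transgenic array lay below every wild type array. The list was lower in camera at an adjusted p of 3.81e-22, and at adjusted p = 0.384 with an estimated correlation. The mean of the list was 9.01 ± 0.20 in wild type and 8.23 ± 0.19 in transgenic lesions (SD, n = 3), a difference of -0.77 (SE 0.16). Its exact permutation p was 0.1, the smallest that 3 against 3 can give. The precursor, newly formed oligodendrocyte, neuroblast, sex-linked and growth factor lists reached the same value, the last without a call in camera. Leaving out any single array kept the mean difference of the myelin list between -0.87 and -0.67. The groups also differed in sex and in region markers, as given below, and in the female arrays alone the difference was -0.57, resting on 1 transgenic lesion.

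**Figure D1:**
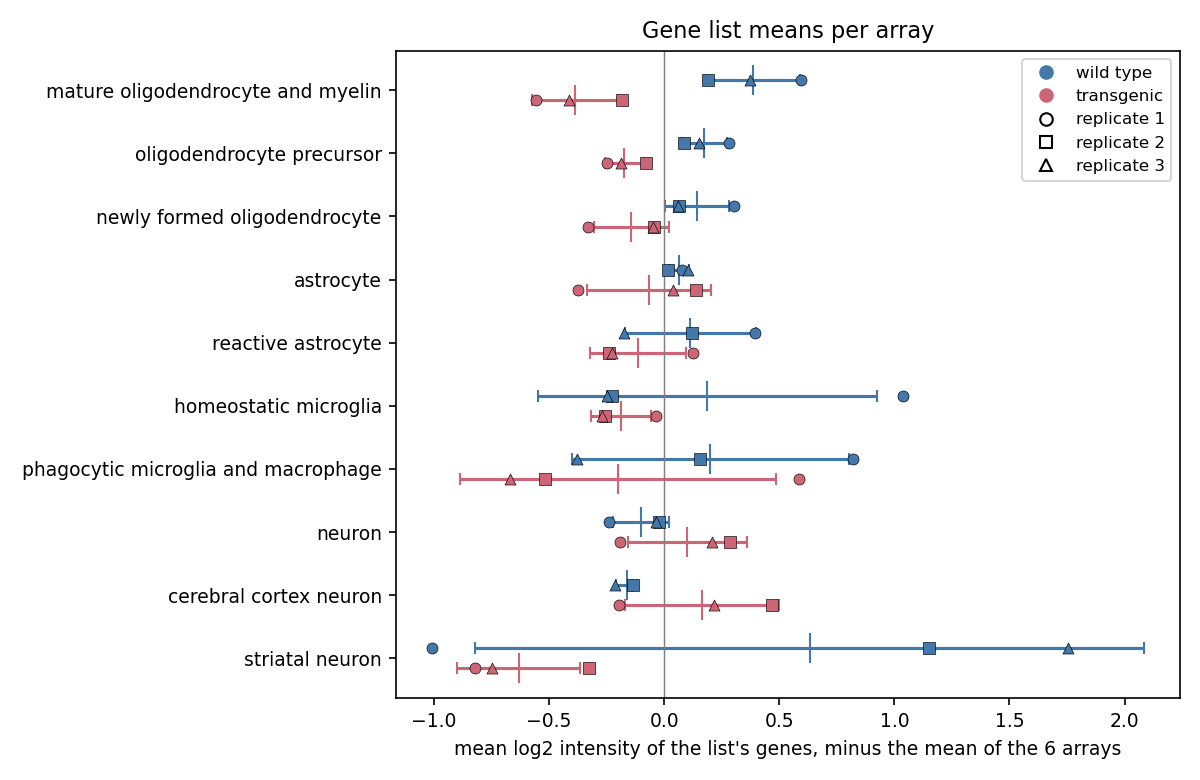
Mean log2 intensity of the genes of 10 lists on each array, minus the mean of the 6 arrays (horizontal axis), for wild type (blue) and transgenic (red) lesions; vertical ticks are group means, bars the SD over 3 arrays, and marker shapes the replicate numbers. The myelin, precursor and newly formed oligodendrocyte lists separate the groups, the myelin list with means of 9.01 and 8.23 before centring. The homeostatic microglia and striatal lists spread widely within the wild type group, and the phagocytic list within both groups.

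Lists of earlier stages of the oligodendrocyte lineage were also called lower in camera at the preset correlation, but not with an estimated correlation. The precursor list had a median difference of -0.38, with 11 of 12 measured members lower. Sox10, a transcription factor of the whole lineage, was 1.68-fold lower (-0.75, SE 0.17) and fell when adjusted over the list alone, the only one of the 12 to do so. Olig2, another lineage factor, stood at 7.71 ± 0.25 and 7.00 ± 0.52 (SD, n = 3), Olig1 differed by -0.36 and Gpr17, a receptor of committed precursors, by -0.66. Pdgfra, the growth factor receptor of precursors, differed by -0.40 (SE 0.24). Of the remaining members, Cacng4 differed by -0.48 and Nkx2-2 by -0.41. Smaller differences were seen for Matn4 (-0.20), C1ql1 (-0.19), Cspg4 (-0.12) and Lhfpl3 (-0.003), and Neu4 was higher (0.14). As Sox10 and Olig2 are factors of the lineage, the list cannot tell precursors from later cells. This list was lower in camera at an adjusted p of 1.56e-04, and at adjusted p = 0.384 with an estimated correlation.

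For newly formed oligodendrocytes the median difference was -0.36, with 10 of 12 members lower. Bcas1, a marker of early myelinating cells, was 1.90-fold lower (-0.92, SE 0.20) and was the only member to fall when adjusted over the list alone. Tns3 differed by -0.65, Mpzl1 by -0.46 and Rras2 by 0.67. The list was lower in camera at an adjusted p of 0.00196, and at adjusted p = 0.704 with an estimated correlation. Both lists kept their call in camera without each array in turn, but not with sex as a covariate, a fit that rests on transgenic replicate 2 alone, where the adjusted p was 0.066 for precursors and 0.165 for newly formed oligodendrocytes.

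**Figure D2:**
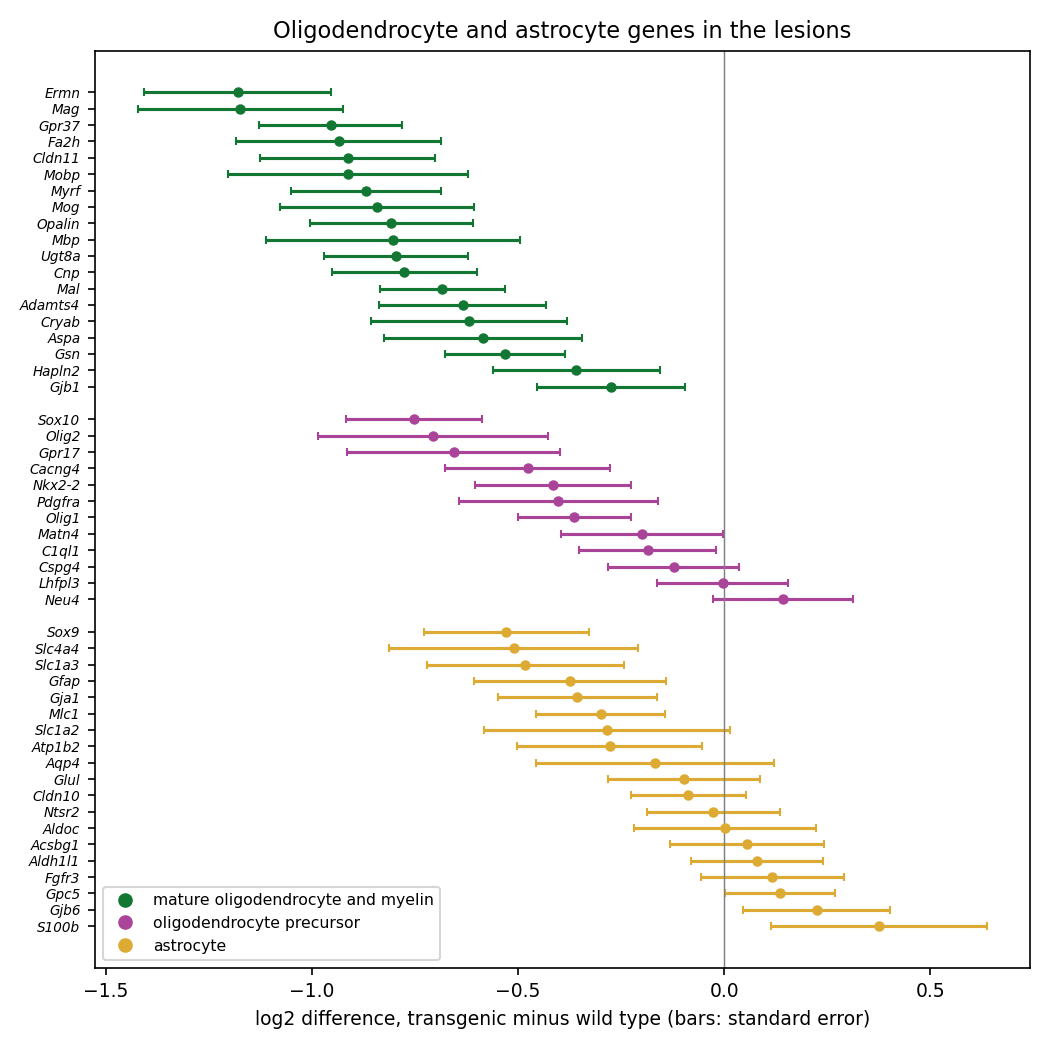
Log2 difference, transgenic minus wild type (horizontal axis; bars are standard errors of the limma fit), for each measured gene of the mature oligodendrocyte and myelin list (green), the oligodendrocyte precursor list (purple) and the astrocyte list (yellow), 3 arrays per group. All 19 myelin genes lie below 0, with a median of -0.80, and the 19 astrocyte genes lie on both sides of 0, with a median of -0.10.

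Astrocyte transcripts were not called as a list, and their members went both ways. Gfap, the intermediate filament whose expression defines the targeted cells, stood at 9.37 ± 0.40 in wild type and 8.99 ± 0.22 in transgenic lesions (SD, n = 3), a difference of -0.37 (SE 0.23) at an adjusted p of 0.695 in limma. The water channel Aqp4 differed by -0.17 (SE 0.29), the glutamate transporter Slc1a3 by -0.48 (SE 0.24) and the folate enzyme Aldh1l1 by 0.08 (SE 0.16). Sox9, a transcription factor of astrocytes, differed by -0.53 (SE 0.20, adjusted p 0.524), Mlc1 by -0.30 (SE 0.16, adjusted p 0.633) and the connexin Gja1 by -0.36 (SE 0.19, adjusted p 0.646). In these 3 every transgenic array lay below every wild type array, whereas in Gpc5 (difference 0.14, SE 0.13) every transgenic array lay above. Across all probe sets, the groups did not overlap for 16.1%. Of 19 measured members, 12 were lower and 7 higher, and 0 passed when adjusted over the list alone or over all probe sets. The mean of the list differed by -0.13 (SE 0.16) with an exact permutation p of 0.7, and camera gave an adjusted p of 0.129. The list was called lower after quantile normalization (adjusted p = 0.0318) and without transgenic replicate 2 (0.00726). Without transgenic replicate 1 the sign turned, with a difference of 0.02.

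The reactive astrocyte list, genes that astrocytes raise after injury, had a median difference of -0.22 with 14 of 16 members lower. S1pr3, a lipid receptor, differed by -0.71, the intermediate filament Vim by -0.67 and the matrix protein Tnc by -0.30; 0 members passed when adjusted over the list alone. Camera gave an adjusted p of 0.00931, and adjusted p = 0.704 with an estimated correlation. The call was lost without wild type replicate 1 (adjusted p = 0.306), transgenic replicate 2 (0.136) or transgenic replicate 3 (0.0937). Of apoptosis genes, Casp9, the initiator caspase of the mitochondrial pathway, stood at 6.52 ± 0.12 and 6.57 ± 0.14 (SD, n = 3). Bid differed by 0.44, Cdkn1a by 0.31, Apaf1 by -0.39 and Fas by -0.37, and the list's 11 members had a median difference of -0.13 at an adjusted p of 0.384 in camera.

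Microglial and macrophage transcripts varied widely within the groups. Cd68, a lysosomal protein of phagocytes, stood at 9.87 ± 1.03 in wild type and 9.20 ± 1.22 in transgenic lesions (SD, n = 3), and Aif1, a marker of microglia and macrophages, at 7.28 ± 0.52 and 7.46 ± 0.73. In the phagocytic list, 17 of 21 members were lower, with a median difference of -0.35; Csf1 and the tetraspanin Cd9 each differed by -0.59, the integrin Itgax by -0.53 and the lipase Lpl by -0.75. The list mean on single arrays was highest in wild type replicate 1 (8.80) and transgenic replicate 1 (8.57). Camera gave an adjusted p of 0.00323, and adjusted p = 0.704 with an estimated correlation. The call was lost without wild type replicate 1 (adjusted p = 0.469), transgenic replicate 2 (0.145) or transgenic replicate 3 (0.232).

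All 11 members of the homeostatic microglia list had lower means in transgenic lesions, with a median difference of -0.28. Sall1, a transcription factor of resident microglia, differed by -0.52, the receptor Csf1r by -0.61, Selplg by -0.62 and Tmem119 by -0.26; 0 passed when adjusted over the list alone. Camera gave an adjusted p of 0.00647, and adjusted p = 0.704 with an estimated correlation. One wild type array carried this list: its mean was 8.83 in wild type replicate 1 and between 7.52 and 7.75 on the other arrays. Without it the direction turned, at an adjusted p of 0.878, and the call was also lost without transgenic replicate 2 (adjusted p = 0.052) or 3 (0.059).

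Markers of infiltrating cells gave no call with all 6 arrays. The neutrophil, T and NK cell and B and plasma cell lists had low mean levels, 4.62, 4.88 and 5.05 in wild type lesions. In transgenic lesions the levels were 4.52, 4.85 and 5.01. All lay below the array medians of 5.34 to 5.59. Without detection calls, the lack of a call for these lists cannot be read as equal infiltration. The monocyte and macrophage list had a median difference of 0.00 over 15 members (camera adjusted p 0.677); Pf4 differed by 0.52 (SE 0.14), Chil3 by -0.29 and Itga4 by 0.29. The neutrophil list differed by a median of -0.13 (adjusted p 0.274), with Mmp9 at -0.20, the T and NK cell list by -0.03 (0.947), with Cd2 at 0.32, and the B and plasma cell list by -0.01 (0.815), with Ighm at -0.36, where 5 of its 7 probe sets were lower and 2 higher. Without transgenic replicate 1 the neutrophil list was called lower (adjusted p = 0.0108). Camera set the T and NK cell list's direction as higher although its median and mean were below 0.

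Mean differences of the neuronal lists were positive for cortical and general neurons and negative for striatal neurons. None of these lists was called with an estimated correlation. Lamp5, a gene of cortical interneurons and upper-layer neurons, was 2.07-fold higher in transgenic lesions (1.05, SE 0.25) and rose when adjusted over the cortical list alone. All 8 measured cortical genes had higher means, with a median difference of 0.20; Tbr1 differed by 0.38, Neurod6 by 0.34 and Cux2 by 0.22. Camera gave this list an adjusted p of 0.00647, and adjusted p = 0.704 with an estimated correlation; the call was lost without transgenic replicate 2 (adjusted p = 0.188) or 3 (0.059). In the general neuron list 12 of 15 members were higher, with a median of 0.17. Nefh, a neurofilament, differed by 0.53, Nefl by 0.48, Nefm by 0.44 and Slc17a6, a glutamate transporter of vesicles, by 0.71. Its adjusted p in camera was 0.00647, with adjusted p = 0.704 when the correlation was estimated. That call was lost without wild type replicate 1 (adjusted p = 0.0945), transgenic replicate 2 (0.166) or transgenic replicate 3 (0.095).

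Genes of striatal neurons were high in wild type replicates 2 and 3 and low on the other 4 arrays. Drd2, a dopamine receptor of striatal neurons, stood at 5.67, 8.11 and 8.68 in wild type replicates 1, 2 and 3 and at 5.83, 6.37 and 5.78 in transgenic replicates 1, 2 and 3. Over the groups, Drd2 differed by -1.49 (SE 0.71), Drd1 by -1.09, Rgs9 by -1.48 and Gpr6 by -1.41, and all 7 members were lower with a median of -1.41. Camera called the list lower at an adjusted p of 1.56e-04, with adjusted p = 0.704 when the correlation was estimated. The exact permutation p of the list mean was 0.4. The list mean of wild type replicate 1, at 6.04, lay below those of transgenic replicates 1, 2 and 3, at 6.22, 6.72 and 6.30.

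Genes of neuroblasts and the subventricular zone, a stem cell niche beside the striatum, were lower in all 8 measured members, with a median difference of -0.56. Igfbpl1 was 1.55-fold lower (-0.63, SE 0.14) and fell when adjusted over the list alone; Sp9 differed by -0.44, Dlx2 by -0.52 and Dlx5 by -0.72. Camera gave an adjusted p of 2.08e-05, and adjusted p = 0.547 with an estimated correlation. This list was also highest in wild type replicates 2 and 3, with means of 6.60 and 6.83 against 6.20 in wild type replicate 1 and 5.88 to 6.16 in transgenic lesions. Ependymal genes had a median difference of -0.01 (adjusted p 0.0737), with Ak7 at -0.64 and Ccdc153 at -0.56, and were called lower without transgenic replicate 1 (0.00419), wild type replicate 1 (0.0342) or wild type replicate 3 (0.0112). The choroid plexus list differed by -0.08 (adjusted p 0.278), with Clic6 at -0.45.

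The sexes of the lesions were unequal. Xist, the RNA of the inactive X chromosome, was high on all 3 wild type arrays (9.30 to 9.49) and in transgenic replicate 2 (9.14), and low in transgenic replicates 1 (4.67) and 3 (4.42). The Y-linked genes Eif2s3y, Uty and Kdm5d showed the opposite, so that 3 of 3 wild type but 1 of 3 transgenic lesions carried a female profile. Adjusted over this list alone, Xist fell and the 3 Y-linked genes rose. Camera gave the list an adjusted p of 0.0298, and adjusted p = 0.547 with an estimated correlation. The call was lost without transgenic replicate 1 (adjusted p = 0.134) or 3 (0.0937).

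**Figure D3:**
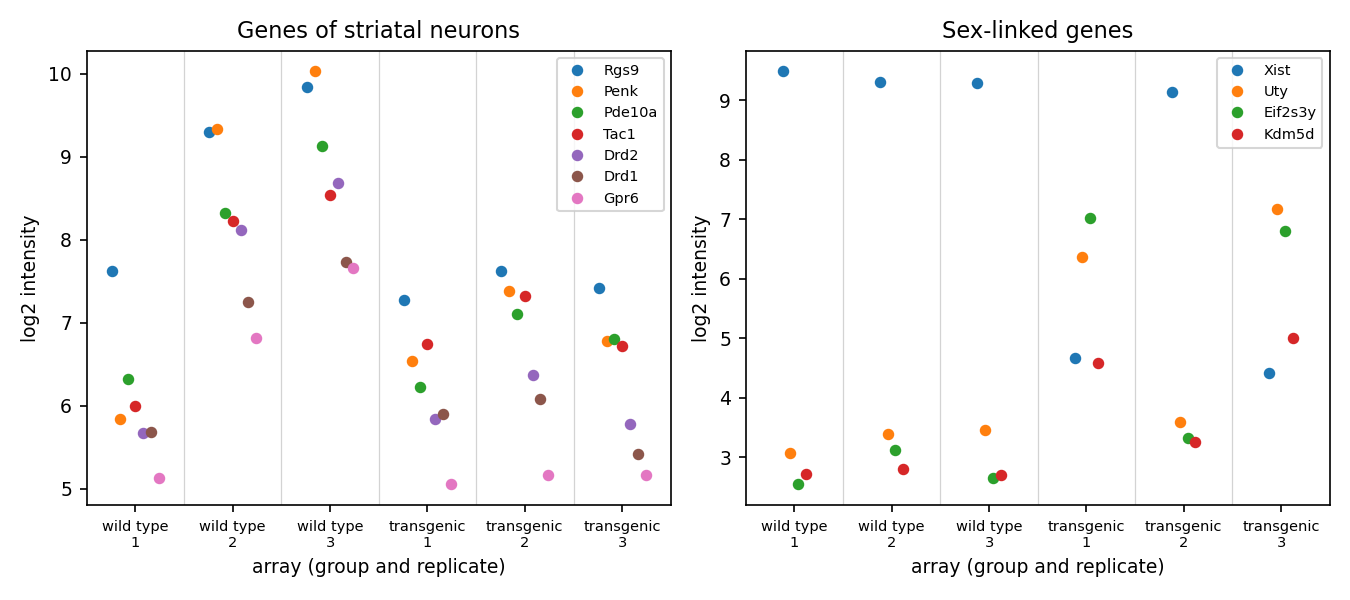
Log2 intensity (vertical axes) of each measured gene of the striatal neuron list (left) and the sex-linked list (right) on each of the 6 arrays (horizontal axes), 1 point per gene and array. Striatal genes are highest in wild type replicates 2 and 3, where Drd2 stands at 8.11 and 8.68, and Xist is low in transgenic replicates 1 and 3, at 4.67 and 4.42.

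Proliferation genes were lower in 12 of 13 members, with a median difference of -0.25. Mki67, a marker of cycling cells, differed by -0.46, Ccna2 by -0.63, Bub1 by -0.43 and Top2a by -0.41, and 0 passed when adjusted over the list alone. Camera gave an adjusted p of 0.00351, and adjusted p = 0.704 with an estimated correlation; the call was lost without transgenic replicate 2 (adjusted p = 0.145) or 3 (0.059). Among complement genes, C4b, a component of the classical pathway, was 1.93-fold lower (-0.95, SE 0.20) and fell when adjusted over the list alone, while the list had a median of -0.16 (adjusted p 0.264). Complement genes were called lower without transgenic replicate 1 (adjusted p = 0.015) or wild type replicate 3 (0.0289).

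Matrix and vessel genes were mixed. In the fibroblast and collagen list Dcn and Lum, both small leucine-rich proteoglycans, rose when adjusted over the list alone, Lum by 0.73 (SE 0.18), whereas Col6a1 differed by -0.55; the median was -0.01, the mean 0.17 and the adjusted p in camera 0.384, toward higher, and 0.0219 without wild type replicate 2. The lectican and perineuronal matrix list had a median of -0.14 (adjusted p 0.0694), with Vcan, a proteoglycan made by oligodendrocyte precursors, at -0.60 and Ptprz1 at -0.36; it was called without transgenic replicate 2 (0.0214) or wild type replicate 3 (0.0351). The endothelial list differed by a median of 0.00 (adjusted p 0.829), with Itm2a at 0.75 and Slc2a1 at -0.29, whose 2 probe sets disagreed in direction, and the pericyte and smooth muscle list by -0.01 (0.792), with Pdgfrb at -0.20.

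No other process gave a call with all 6 arrays. The interferon list had a median of -0.09 (adjusted p 0.129 in camera), with Bst2 at -0.58, and the cytokine and chemokine list -0.09 (0.815), with Lif, a cytokine that acts on oligodendrocytes, at -0.39 and Cxcl1 at 0.60. Antigen presentation differed by -0.07 (0.747), with H2-Eb1 at 0.31. Cholesterol synthesis, which supplies myelin membrane, differed by -0.13 (0.168), with Dhcr7 at -0.28, and cholesterol efflux and lipid storage by -0.24 (0.0524), with Abca1 at -0.54. Among growth factors and signals to the oligodendrocyte lineage, the median was 0.07 (0.264), with Id4 at -0.61, Id2 at 0.45 and Shh at 0.43. Immediate early genes differed by 0.17 (0.0647), with Egr1 at 0.39, and the reference genes by -0.10 (0.746), with Gapdh at -0.02 and Actb at -0.38. Calls appeared without transgenic replicate 1 for interferon (adjusted p = 0.00419), cytokines, immediate early genes and cholesterol efflux (0.00879 each). They also appeared without wild type replicate 3 for immediate early genes (0.0323) and cholesterol efflux (0.00117), and without transgenic replicate 2 for cholesterol synthesis (6.75e-04).

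Of 33 lists tested, camera called 9 lower and 3 higher, and none with an estimated correlation or in fry, where the smallest adjusted p-values were 0.384 and 0.116. The 3 higher calls included the sex-linked list, in which Xist was lower and 3 Y-linked genes were higher. Its direction only reflects that the Y-linked genes outnumber Xist. Of the 12 calls, 5 were kept without each array in turn: the 3 oligodendrocyte lists, the striatal list and the neuroblast list. The striatal list was kept although it was high only in wild type replicates 2 and 3 (exact permutation p 0.4). Keeping a call in this way therefore does not tell a group difference from a few deviating arrays. Other ways of splitting the 6 arrays into 3 and 3 called 5 to 16 lists.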

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

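The settings with sex, with subsets of arrays, with list means as covariates or with autosomal probe sets were chosen after seeing the data. The adjusted count of 0 probe sets was also 0 under both normalizations, both filters, 1 probe set per gene, trend and robust, the threshold of 0.10, the plain t-test, autosomal probe sets alone, the striatal covariate and leaving aside wild type replicates 2 and 3. It was 2611 with array weights, which gave transgenic replicate 3 a weight of 7.67 and transgenic replicates 1 and 2 weights of 0.284 and 0.258, 1481 with sex as a covariate, 1843 in the female arrays alone, 37 with the cortical covariate, and 0 to 335 without each array. No wild type array was male, so both sex settings compare transgenic replicate 2 alone with the wild type arrays, and leaving aside wild type replicates 2 and 3 leaves wild type replicate 1 alone. In each, the lone array is assumed to vary like the arrays that give the spread, so these counts and p-values measure 1 array and not a group. The 3668 probe sets at an unadjusted p under 0.05 became 2243 above the median level, 1971 with 1 probe set per gene and 1968 on autosomes, where fewer were tested, 10793 with array weights, 8604 with sex, 10602 in female arrays, 6706 with the cortical covariate, 1470 leaving aside wild type replicates 2 and 3, and 2031 to 5168 without each array. The 1950 with at least 1.5-fold became 1125, 613 and 616 under those smaller sets, 6850 with sex, 7367 in female arrays and 4137 with the cortical covariate. Except where fewer probe sets or arrays were used, the cause was not tested. The 12 calls among gene lists became 0 with an estimated correlation and 0 in fry, and 5 to 18 without each array. With sex as a covariate 6 of the 12 were lost, 5 other lists were gained and 1 turned; those lost were precursors (adjusted p = 0.066), newly formed oligodendrocytes (0.165), homeostatic microglia (0.0959), striatal neurons (0.103), neuroblasts (0.066) and sex-linked genes (0.301). In female arrays 7 were lost and 4 gained, and with the cortical covariate 3 were lost, 3 gained and 5 turned. The loss for sex-linked genes was fixed in advance, because these genes set the sex covariate. So was the result of the cortical list with its own mean as the covariate. The myelin list's adjusted p of 3.81e-22 became 0.384 with an estimated correlation and 0.116 in fry. It stayed past the threshold in all other settings run, from 1.58e-26 to 1.07e-05. Its mean difference of -0.77 became -0.57 with sex as a covariate and in female arrays, and -0.98 leaving aside wild type replicates 2 and 3. The astrocyte difference of -0.13 became 0.071 in both sex settings and -0.38 with the cortical covariate. Lists that turned direction and were called before or after were homeostatic microglia without wild type replicate 1 (adjusted p = 0.878, and 3.03e-05 at the lowest without another array), striatal neurons leaving aside wild type replicates 2 and 3 (0.0321) and, with the cortical covariate, phagocytic microglia (0.668), neurons (0.92), cortical neurons (0.871), proliferation (0.871) and cytokines (0.00282). For T and NK cells only the direction that camera gives turned, to lower with sex as a covariate (0.0495); their mean difference was already below 0. Lists called neither before nor after also changed sign, up to 9 in a setting, with the cortical covariate; without transgenic replicate 2 there were 7. Of the 155 named genes, 122 kept their direction wherever fitted, among them all 20 chosen for non-overlap. Leaving out arrays could not turn these 20. With the replicate block 0 probe sets passed, 2999 had an unadjusted p under 0.05 and 15 lists were called, 3 more than without it. The replicate numbers did not pair the arrays: deviations of equally numbered arrays from their group means correlated at 0.012, -0.098 and -0.068, and none correlated best with its own number.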

Other observations

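The covariate tests of the myelin list, their bounds and the count of splits for that list were chosen after the results were seen. The further striatal list was written before its values were seen.

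The myelin list was lower in the transgenic lesions by -0.77 (95% confidence interval -1.22 to -0.33), and 3 technical explanations were weighed. With the striatal list mean as a covariate, for striatal tissue in some wild type arrays, the difference was -0.88 (-1.53 to -0.22), and with the cortical list mean, for more cortical grey matter in the transgenic arrays, -0.95 (-1.53 to -0.36). Both intervals exclude 0, but the bound first set asked for a whole interval below -0.4, which neither met. It was relaxed to 0 after these values were seen. The fits also assume that the myelin list follows the covariate alike in both groups. Wild type replicate 1 had a low striatal mean (6.04) with the highest myelin mean (9.21). Transgenic replicate 1 had the lowest myelin mean (8.06) at a cortical mean of 7.85, within the wild type range. The cortical list holds neuron genes only and does not measure the share of white matter. These fits therefore cannot decide, and both explanations stay open, in whole or in part. With sex as a covariate the difference was -0.57 (-1.21 to 0.08), so a difference of sex stays open, resting on 1 female transgenic lesion, and each fit left 3 residual degrees of freedom. Of the 10 splits of the 6 arrays, 1, the real one, gave a difference this large, 0.77 against at most 0.52 in the others, but 10 splits cannot give a share under 0.05. The removal of astrocytes that the design names stays open too, untested as a cause of the myelin difference. The astrocyte list itself was not called lower with all 6 arrays (difference -0.13, SE 0.16, exact permutation p 0.7), so a loss of astrocytes was not clear in these data.

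Striatal genes stood high in wild type replicates 2 and 3, and a candidate explanation is that these dissections held striatal tissue. Of 14 genes in the further striatal list, none of them in the first, 13 had these 2 arrays as their highest pair, where the median of 10000 random lists matched on level was 1 and the highest was 5. As examples chosen after their values were seen, Pde1b and Gng7 stood at 9.01 and 9.22 in wild type replicate 2 and at 9.40 and 9.29 in wild type replicate 3, against at most 8.10 and 7.79 on the other arrays. A genotype effect on these genes stays open, although wild type replicate 1 lay with the transgenic arrays.

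For counts over all probe sets, 10 splits cannot give a share under 0.05. The real split gave 3668 probe sets at an unadjusted p under 0.05 against at most 2463 in the others, and 1950 with at least 1.5-fold against at most 1113, so that 1 split of 10 was as large for each. All 10 splits gave 0 after adjustment in limma. Camera at the preset correlation called 12 lists in the real split and up to 16 in others, with 5 of the 10 splits calling at least as many. The myelin list's adjusted p reached 1.54e-10 in another split, against 3.81e-22 in the real one.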
